A study of Mus musculus with 302 samples.

How the data were processed

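Each of 302 arrays compared the liver RNA of 1 mouse, labelled Cy3, with a common pool labelled Cy5, per the labels. RNA was extracted on spin columns with a DNAse step and labelled by an automated aminoallyl amplification, per the labels' protocols. Feature extraction, background correction and normalization are not given in the sources used here. The authors deposited 1 table of log ratios, with 23562 probes and 302 columns, and every column was matched to a mouse by its label. The log base and the direction of the ratio are not stated. The deposited values end at -2 and 2, a 100-fold ratio in log10, and 546 and 472 values lie at the upper and the lower end. In the 160 mice of the upper marker cluster the medians of the Y-linked genes Eif2s3y and Kdm5d were 0.195 and 0.181. If only these 53.0% of the mice carried the RNA, their ratio to the pool would be 0.276 in log10, 0.917 in log2 and 0.635 in natural log, and the log10 value is the nearest. In the other 142 mice the medians were -1.73 and -1.17. Over the 400 probes with the widest spread the mean of the linear ratio had a median of 1.09, near the 1 that a pool of equal shares gives, and the mean of its inverse one of 1.67. The values were therefore read as log10 of mouse over pool, which is likely but not stated. The lowest correlation between arrays over all probes was -0.508, and 879 of 45451 pairs lay under -0.3. Every array has the same dye orientation, so the direction was kept. Array medians ran from -0.0117 to 0.0174, and the SD over an array's probes from 0.0696 to 0.258 with a median of 0.0975. The deposited values were used without further normalization.

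Probe names came from an annotation table of the array and were updated through gene identifiers to a mouse gene table of the assembly GRCm38.p6. Of the probes, 13655 had 1 symbol, 48 had several and 9859 were not listed in it. The symbols of 12652 probes matched 10838 genes, 1003 had an identifier outside the mouse table and stayed unnamed, and probes with several symbols were not named. The gene table served for names and for the order of genes, and its older symbols were kept. The build of the array design is not known, so no coordinates are given. Probes with values in at least 90% of the mice were used, 23512 in all, and 0.0831% of all values were missing.

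The labels give 1 group, and each mouse has a number between 51 and 362 in its title. The mean of the standardized values of Eif2s3y and Kdm5d, the measured part of 5 sex chromosome genes fixed for this, parted the mice by 2-means into clusters of 142 and 160 with a gap of 0.952 between them. These marker clusters entered only as a block, no sex was assigned, and no gene was tested between the clusters. In 50 probes every mouse of a block was missing. The mouse number that best parted these probes lay between 212 and 213, and together with the marker cluster it gives 4 blocks of 77, 65, 82 and 78 mice. The order in which the mice were deposited keeps each of these 4 blocks together. These blocks point to separate processing before deposit, and values within them are given beside some of the correlations.

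The spread of a probe was its SD over mice with a 95% interval from 1000 bootstraps of mice, and a probe counted as varying widely when the lower bound was over 2 times the median SD. Separate clusters were fitted per probe as 1 against 2 Gaussian components of equal variance. A probe counted when the Bayesian information criterion fell by over 10, the means lay over 3 within-component SDs apart and the smaller component held at least 5% of the mice. Mice in the clusters of a probe were counted and set against 1:3 by an exact binomial test, and those of a fit with 3 equally spaced components, where it was better by over 10 and each held at least 5% of the mice, against 1:2:1 by a chi-square test. Lists of genes for 31 pathways, cell types and functions were fixed before the data were examined, and 30 had at least 3 measured genes. For each, the mean Pearson r over pairs of genes within each marker cluster, averaged over both, was compared with 10000 random lists of the same size and spread (one-sided), with the Benjamini-Hochberg adjustment over lists and an SE from 200 bootstraps of mice. Each member was correlated with the mean of the rest of its list, and 40 fixed pairs of genes were correlated in each marker cluster, by Pearson's r and Spearman's rho with 100000 permutations (two-sided), again without the 2 mice farthest from the median of the first measure. A pair counted when both clusters had an adjusted p under 0.05 and the same sign.

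Slopes on the mouse number, with marker cluster as a covariate, and means against the pool were tested with limma 3.58.1 in R 4.3.3, two-sided, with the Benjamini-Hochberg adjustment at 0.05. Probes of a gene were compared by the median over genes of their correlation, against 1000 draws of random probes of similar spread. Adjacent genes were compared by their mean squared r minus that of pairs on different chromosomes, against 1000 orders of the genes, leaving out pairs whose symbols start with the same letters. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.

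By a rule written before the data were examined, the genes named are the 25 with the largest SD, the 20 with the widest separation of clusters, 2 members of each list with the highest mean correlation to the rest and 2 with the largest SD, all genes of the fixed pairs, the sex chromosome genes, the 3 genes with a known parental difference, 5 with the largest slope in each direction and the 5 adjacent pairs with the largest r. A gene with several probes is their mean in lists and pairs and its most variable probe otherwise. List members that ran against their list and Dgkq were named after their values were seen.

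Alternatives covered array centring, quantile normalization, a lower limit on present values, 4 arrays that stand apart by their SD, the lower and the upper 50% of mouse numbers, extreme values pulled in to 3 robust SDs, other thresholds, rank correlation, principal components and the choice of probe. Removal of the block means, of the marker cluster means and of the slope on the number, the range of numbers as a covariate, a smaller component of at least 10% and the dip between clusters were chosen after seeing the data, as were the member correlations and the counts of slopes per list. The steps were tested on simulated data. Seeded probes of 3 times the SD were all recovered (100% of 200) with 0 others called. Values from 1 normal distribution gave separate clusters in 0% and from a t distribution in 0.15% of 2000 rows, but lognormal values did in 68%, and 2 components 3 and 4 SDs apart were found in 55.5% and 100% of 200 rows. All 20 seeded lists and 0 of 20 unseeded ones passed, 7% of 200 unseeded pairs had a p under 0.05, and 200 seeded pairs gave a median r of 0.500. Probes made to share a part giving r = 0.5 gave 0.498 over 1150 genes, and neighbouring genes without linkage gave p = 0.222. With limma, 92.5% of 200 seeded slopes and 14 of 23312 others were called, and 1 of 23512 probes without a mean.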

Results

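Liver RNA from 302 F2 mice was measured on 2-colour arrays, 1 array per mouse. Each was set against a common pool described as equal shares of the RNA of all of them. The mice came from an intercross of the inbred strains C57BL/6J and C3H/HeJ run in both directions, and the series was made to study the genetics of gene expression. They ate chow with 4% fat until 8 weeks of age and then a Western-type diet with 42% fat and 0.15% cholesterol for 12 weeks. Livers were taken at 20 weeks after a 12 h fast. The labels give 1 group and no sex, direction of the cross, genotype or trait for a mouse, so no groups of mice were compared. Each value was read as the log10 ratio of a mouse to the pool, although neither base nor direction is stated, for 1 of 23562 probes, of which 12652 carry the name of 1 of 10838 mouse genes. Each gene's spread among the mice, the genes that move together and the genes whose values fall into separate clusters are described in turn. Array medians lay between -0.0117 and 0.0174, and the number of arrays limits the precision.

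The 25 genes with the largest spread among the mice included enzymes of steroid, sulfate and drug metabolism and genes of many other kinds. The spread of Sult2a1, a sulfotransferase, was 0.879 in log10 units (SD, 95% bootstrap interval 0.848 to 0.905, n = 302), and its 5th and 95th percentiles lay 160-fold apart. The sulfotransferase Sult3a1 (SD 0.838, 0.807 to 0.866), the plasma glycoprotein gene A1bg (SD 0.882, 0.844 to 0.912), the steroid dehydrogenase Hsd3b5 (SD 0.772, 0.737 to 0.805) and the hydroxyacid oxidase Hao2 (SD 0.765, 0.735 to 0.788) stood close to it. Cidea, a lipid droplet protein that appears in fatty liver, had an SD of 0.775 (0.724 to 0.822) and percentiles 192-fold apart. The Y-linked genes Eif2s3y (SD 0.955, 0.934 to 0.970) and Kdm5d (SD 0.687, 0.671 to 0.701) were also among the 25 genes with the largest SD.

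A clear gap in Eif2s3y and Kdm5d parted the mice into 2 marker clusters of 142 and 160, which served only as a block. With the mean of each marker cluster removed, 12 of these 25 genes lost more than 50% of their SD. Sult2a1 went to 0.280, Sult3a1 to 0.293, A1bg to 0.341, Hao2 to 0.272, and the transporter Slc22a26 to 0.209. The fatty acid hydroxylase Cyp4a12a went to 0.175, the fatty acid elongase Elovl3 to 0.244, and the acetyltransferase Nat8 and the matrix protein gene Omd to 0.213 each. The rest of the 12 were Eif2s3y (0.156), Kdm5d (0.143) and the cytochrome P450 Cyp2b13. Another 9 genes kept over 90% of it. They were the homeobox genes Lhx1 (0.779) and Hoxc11 (0.578), the inflammation regulator Nlrp12 (0.692), the olfactory receptor gene Olfr707 (0.622), the mucosal glycoprotein gene Dmbt1 (0.591), and the DNA polymerase subunit Pold3 (0.569). The others were the kinase subunit Camk2b (0.554), the splicing factor Rbfox1 (0.509) and the membrane protein gene Tmc5 (0.503). Cidea (0.594), Hsd3b5 (0.491), the pseudogene Serpina4-ps1 (0.426) and the steroid hydroxylase Cyp17a1 (0.352) lay between. Signal over background is not part of the deposited values, so spread near background cannot be told apart from spread in RNA. A value at the limits of -2 or 2 occurred in 544 probes. By the median absolute deviation all 25 genes fell outside the interval of their SD.

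**Figure D1:**
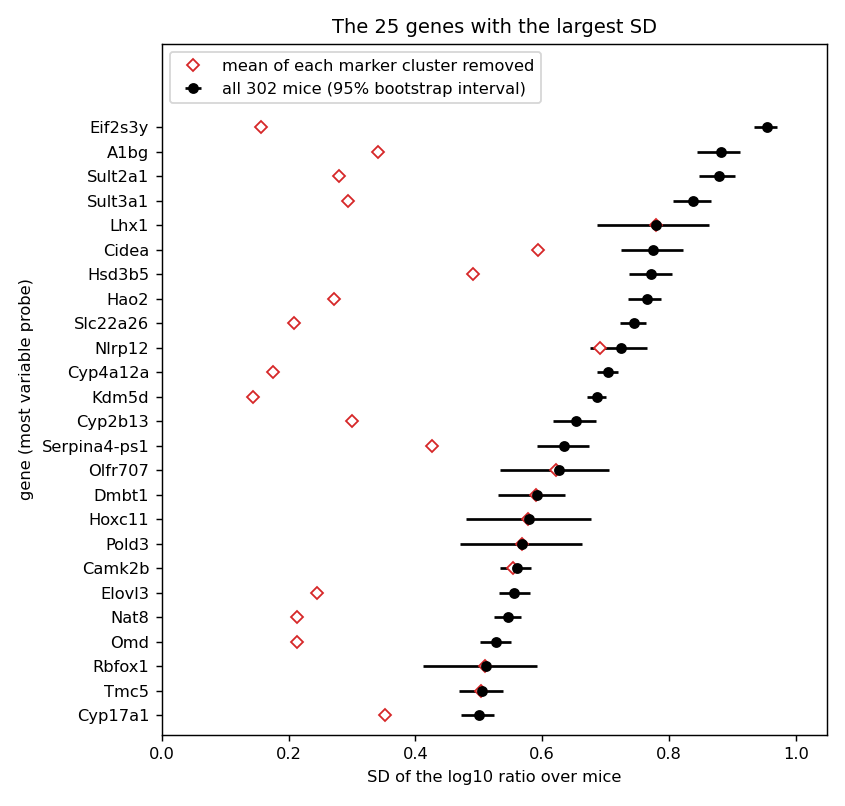
SD over the 302 mice of the log10 ratio to the pool for the 25 genes with the largest SD, each by its most variable probe. Black points are the SD with its 95% bootstrap interval and open diamonds the SD with the mean of each marker cluster removed, which falls from 0.879 to 0.280 for Sult2a1 and stays at 0.779 for Lhx1.

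Across all probes the median SD was 0.0661, a 1.16-fold spread. In 1684 of 23512 probes (7.16%) the lower bound of the SD was over 2 times that median, a threshold of 0.132 or 1.36-fold, and these belonged to 1018 named genes. With the mean of each marker cluster removed, 42 of them lost more than 50% of their SD and 1299 kept over 90%. Of 3 genes with a known difference between the parent strains, Nnt, the mitochondrial transhydrogenase that is deleted in C57BL/6J, passed with an SD of 0.152 (0.140 to 0.163). Tlr4, the endotoxin receptor that is inactive in C3H/HeJ, had 0.112 (0.101 to 0.124), and the transporter Abcc6 had 0.129 (0.120 to 0.136), and neither passed. With a threshold of 3 times the median SD, the probes that vary widely among mice numbered 514.

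Several genes had a low and a high state among the mice, with about 1 mouse in 4 in the low one. Hsd17b13, a lipid droplet protein of hepatocytes, was 6.48-fold lower in a cluster of 65 mice, whose mean lay 7.75 within-cluster SDs below that of the others. Nlrp12 was 31.3-fold lower in 78 mice, the translation factor partner Paip1 7.46-fold lower in 70 and Xdh, the enzyme that makes uric acid, 5.10-fold lower in 68. The hydrolase family gene Abhd1 was 4.59-fold lower in 65 and Pttg1, the securin of cell division, 5.95-fold lower in 85. None of these counts departed from 1:3 (exact binomial p from 0.184 for Hsd17b13 and Abhd1 to 0.740 for Nlrp12). In the fit to other genes the smaller cluster was the upper: Moxd1, a monooxygenase family gene, was 18.2-fold higher in 19 mice, the potassium channel gene Kcnk1 3.23-fold higher in 19, the mucin gene Muc3 7.34-fold higher in 38 and the microtubule-binding gene Eml2 5.01-fold higher in 16. Dmbt1 was 20.8-fold higher in 65 mice.

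The other 9 of the 20 genes with the widest separation were Eif2s3y, Kdm5d, Cyp4a12a, Cyp4a12b, Slc22a26, Sult2a1, Sult3a1, the neutrophil peroxidase gene Mpo and the aldehyde dehydrogenase Aldh3b1, and none of these had separate clusters once the mean of each marker cluster was removed. Nnt had separate clusters only after that step, with 16.5% of the mice in the smaller, and Tlr4 and Abcc6 had none. In Camk2b, Dmbt1, Muc3 and Lhx1 a fit with 3 equally spaced clusters was better than one with 2 and put at least 5% of the mice in each, and the mice in them departed from 1:2:1. In Moxd1, Kcnk1 and Eml2 it was better too (BIC lower by 103, 40.7 and 40.3, against 13.0 in Camk2b), but the smallest cluster held 8, 7 and 14 mice, under 5%. There were 91, 22 and 189 for Camk2b (chi-square p = 2.12e-62) and 226, 28 and 48 for Dmbt1 (p = 8.39e-90). The kinase gene Dgkq, named after its values were seen, had 84, 158 and 60 mice and did not depart from it (p = 0.107).

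By the fixed rule 1048 of 23512 probes (4.46%) had separate clusters, and 652 of them, with 356 named genes, also had them once the mean of each marker cluster was removed. In 123 of the 652 the fit with 3 clusters was better, in 24 of them with at least 5% of the mice in each cluster, and 5 of those 24 did not depart from 1:2:1. Among the other 628 the smaller cluster held under 10% of the mice in 384 and 20 to 30% in 103, and these 103, with 61 to 90 mice, were those that did not depart from 1:3. The smaller cluster was the lower in 93 of the 103 and the upper in 262 of the 384. Where the clusters lay over 4 SDs apart, 46 of 106 probes did not depart from 1:3 (43.4%). Counts of 61 to 90 mice make up 22.1% of all counts from 5 to 50% of the mice. The 103 of 628 lie below that share and the 46 of 106 above it.

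A single skewed distribution also passes this rule. In simulated lognormal values 68% of 2000 rows were counted, with a median of 8.89% of mice in the smaller cluster and 4 rows with 20 to 30%. No counted row had a dip between the clusters, meaning under 0.5 times as many mice around the midpoint as around the smaller cluster's mean. Hsd17b13, Nlrp12, Paip1, Xdh, Abhd1 and Pttg1 had a dip, but Moxd1, Kcnk1, Muc3, Eml2, Dmbt1 and Lhx1 had none, so the values of these last 6 leave the tail of a single distribution open. A dip is also missed in real clusters: with 1 mouse in 4 it was found in 0% of 200 simulated rows 3 SDs apart, 27% at 4 SDs and 100% at 6. It was present in 99 of the 1048 probes and 56 of the 652, and in 48 of the 53 of these with 2 clusters the counts did not depart from 1:3. The dip is harder to meet where the smaller cluster is small, and 2 of the 384 probes with under 10% had it. Its recovery was simulated only with 1 mouse in 4, so the rule itself may favour counts near 1:3. In 379 of the 652 probes (58.1%) cluster membership also followed the range of mouse numbers (Fisher's exact test), and this held in 32 of the 103 probes near 1:3. Hsd17b13 (38 and 27 mice in the lower and the higher range, p = 0.327), Nlrp12 (43 and 35, p = 0.693), Xdh (37 and 31, p = 0.784), Paip1 (p = 0.339), Pttg1 (p = 0.159), Abhd1 (p = 0.093) and Muc3 (15 and 23, p = 0.0858) gave no p under 0.05. Moxd1 (4 and 15, p = 0.00743), Kcnk1 (5 and 14, p = 0.0302), Dmbt1 (23 and 42, p = 0.00197), Eml2 (14 and 2, p = 0.00401) and Lhx1 (13 and 4, p = 0.0463) did.

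**Figure D2:**
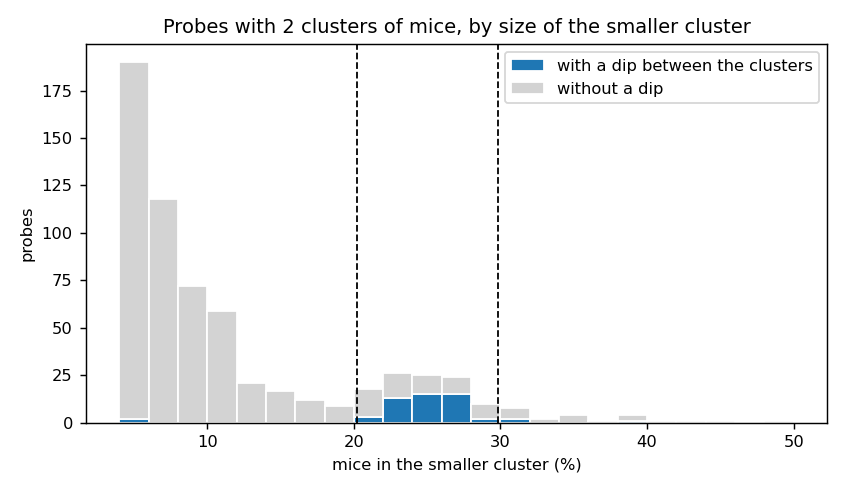
Number of probes by the percentage of the 302 mice in the smaller of 2 clusters, for the 628 probes with separate clusters before and after the mean of each marker cluster was removed. Blue marks the 53 probes with a dip between the clusters, and dashed lines mark 61 and 90 mice, the counts that do not depart from 1:3, between which 48 of the 53 lie.

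Genes of the lipid pathways moved together from mouse to mouse, which was tested over lists of genes fixed for each pathway. Within the marker clusters the mean correlation between genes of cholesterol synthesis and uptake was 0.311 ± 0.0352 (SE, n = 302 mice), and 14 of the 16 measured genes followed the rest of the list. Cyp51 (r = 0.768, rho = 0.654) and Lss (r = 0.746, rho = 0.521), enzymes of sterol synthesis, followed it most closely, and Sqle had the largest spread (SD 0.357) and Dhcr7 the next (0.176). In fatty acid synthesis the mean was 0.241 ± 0.0201 with 13 of 15 genes following. The fatty acid synthase Fasn (r = 0.764, rho = 0.725) and Acly, which makes cytosolic acetyl-CoA (r = 0.656, rho = 0.579), led it. Thrsp (SD 0.311) and the desaturase Scd1 (SD 0.222) had the largest spread. In fatty acid oxidation the mean was 0.229 ± 0.0178 and 14 of 16 followed, among them Ehhadh (r = 0.769, rho = 0.728) and Cyp4a14 (r = 0.735, rho = 0.697). Pdk4 (SD 0.306) and Vnn1 (SD 0.241) spread most there, and the dehydrogenase Acadvl ran against the list (r = -0.130, rho = -0.114, adjusted p = 0.0298).

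All 9 measured genes of lipid droplets and fat storage varied widely, and 8 followed the rest (mean 0.316 ± 0.0160). Closest to the rest were Pparg, a regulator of fat storage (r = 0.741, rho = 0.736), Fitm1 (r = 0.724, rho = 0.715, SD 0.297) and Cidea (r = 0.701, rho = 0.712). Genes of drug metabolism had a mean of 0.273 ± 0.0169 and 13 of 14 followed, among them Cyp2c29 (r = 0.781, rho = 0.771), Cyp2c50 (r = 0.761, rho = 0.768) and Cyp2b10 (SD 0.280), but not Cyp2c55 (r = 0.0237, SD 0.298). Glucose metabolism had a mean of 0.181 ± 0.0194 and 6 of 8 followed. Igfbp1 (r = 0.634, rho = 0.654, SD 0.365) and Pck1, the enzyme that commits carbon to gluconeogenesis (r = 0.588, rho = 0.614), led them, with Ppargc1a next in spread (SD 0.241). In bile acid synthesis and transport the mean was 0.164 ± 0.0156 and 10 of 13 followed, led by the uptake transporter Slco1b2 (r = 0.665, rho = 0.658) and the conjugating enzyme Baat (r = 0.536, rho = 0.544). The largest spread there was in Akr1d1 (SD 0.203) and Cyp8b1 (SD 0.184), and Cyp8b1 did not follow the others (r = 0.0944, adjusted p = 0.118). The call of this list was lost with the first principal component removed (mean 0.0423, adjusted p = 0.112). Apolipoproteins and lipoprotein genes were not correlated as a list (mean 0.0221, adjusted p = 0.349). In it 6 of 13 followed, led by Apoa1 (r = 0.543, rho = 0.509) and Apoc4 (r = 0.382, rho = 0.354), and 3 ran against them. Those were the cholesterol exporter Abca1 (r = -0.569, rho = -0.509), Lpin1 (r = -0.211, rho = -0.180, adjusted p = 0.000375, SD 0.378) and Apoa4 (r = -0.205, rho = -0.181, adjusted p = 0.000507, SD 0.258).

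Among immune genes those of macrophages and Kupffer cells, the resident macrophages of the liver, had a mean of 0.492 ± 0.0165. There 20 of 21 genes followed the rest, led by the complement gene C1qc (r = 0.940, rho = 0.938) and the adaptor Tyrobp (r = 0.935, rho = 0.927), and Gpnmb (SD 0.440) and Marco (SD 0.339) spread most. The leukocyte antigen Cd52 ran against the list (r = -0.254, rho = -0.282). All 7 measured MHC class II genes followed each other (mean 0.454 ± 0.0234, and 0.539 against 0.514 for macrophages in the marker cluster of 142 mice), with H2-DMb2 (r = 0.846, rho = 0.791), H2-Aa (r = 0.835, rho = 0.786, SD 0.172) and H2-Eb1 (SD 0.237). In the acute phase list the mean was 0.392 ± 0.0225 and 15 of 16 followed, led by the serum amyloid genes Saa3 (r = 0.884, rho = 0.903, SD 0.444) and Saa1 (r = 0.878, rho = 0.902, SD 0.440). In the interferon response it was 0.372 ± 0.0170 and 17 of 18 followed, led by Ifit3 (r = 0.853, rho = 0.856) and Ifit1 (r = 0.851, rho = 0.856). The most spread genes were Cxcl10 (SD 0.269) and Gbp3 (SD 0.215). Neutrophil genes had a mean of 0.176 ± 0.0194 and 10 of 11 followed. S100a8 (r = 0.637, rho = 0.591) and S100a9 (r = 0.636, rho = 0.612, SD 0.253) led them, with Ngp next in spread (SD 0.250). Lymphocyte genes had 0.158 ± 0.0147 and 11 of 14 followed, led by Cd3g of the T cell receptor complex (r = 0.655, rho = 0.574) and Ccl5 (r = 0.650, rho = 0.542, SD 0.216), with Klrd1 next in spread (SD 0.192).

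Markers of the other cell types of the liver were correlated too. Stellate cell and matrix genes had a mean of 0.294 ± 0.0239 and 13 of 14 followed, led by Col1a2 (r = 0.780, rho = 0.741) and Lum (r = 0.728, rho = 0.661). The largest spread was in Col1a1 (SD 0.410) and Col5a2 (SD 0.191). Red blood cell genes had 0.239 ± 0.0201 and 6 of 8 followed, led by the globins Hbb-b1 (r = 0.798, rho = 0.810) and Hbb-b2 (r = 0.797, rho = 0.801), and Alas2 (SD 0.272) and Epb42 (SD 0.228) spread most. Bile duct cell genes had 0.236 ± 0.0211 and 5 of 6 followed. Epcam (r = 0.734, rho = 0.611) and the chloride channel Cftr (r = 0.446, rho = 0.291, SD 0.125) led them, and Krt23 did not follow (r = 0.0784, SD 0.288). Endothelial genes had 0.124 ± 0.0164 and 9 of 12 followed, led by Eng (r = 0.640, rho = 0.588) and Emcn (r = 0.548, rho = 0.485). Lyve1 (SD 0.164) and Tie1 (SD 0.121) spread most. Fat cell genes were not correlated (mean -0.00587, adjusted p = 0.483). Lep (r = 0.155, rho = 0.153, adjusted p = 0.00859, SD 0.110) followed its list, and Retn did so by 0.146 (adjusted p = 0.0141) but by 0.0884 without the 2 farthest mice (p = 0.130). Car3 ran against the list (r = -0.273, rho = -0.223, SD 0.206). The exocrine pancreas list did not pass either (mean 0.107, adjusted p = 0.0702), although 5 of its 7 genes followed, or 4 adjusted over the list alone. Prss2 (rho = 0.214) went from r = 0.489 to 0.183 and Cel (rho = 0.196) from 0.419 to 0.157 without the 2 farthest mice, and Cela2a (SD 0.155) and Cpb1 (SD 0.143) spread most.

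Genes of general cell functions formed further groups. All 12 immediate early genes, which respond quickly to stimuli, followed each other (mean 0.396 ± 0.0259), led by Btg2 (r = 0.866, rho = 0.855) and Jun (r = 0.741, rho = 0.733). Egr1 (SD 0.306) and Dusp1 (SD 0.283) spread most. The mean was 0.380 ± 0.0224 in oxidative phosphorylation, where 9 of 10 followed, among them Ndufa2 (r = 0.763, rho = 0.733), Cox7b (r = 0.712, rho = 0.681, SD 0.0967) and Atp5g1 (SD 0.0772). All 10 heat shock genes followed (mean 0.296 ± 0.0221), led by Hsph1 (r = 0.708, rho = 0.668) and Hspa8 (r = 0.658, rho = 0.670). The spread was largest in Hspb1 (SD 0.263) and Hspa1a (SD 0.195). For ribosomal proteins the mean was 0.263 ± 0.0200 and 13 of 14 followed, with Rps18 (r = 0.727, rho = 0.707), Rps15 (r = 0.646, rho = 0.662), Rps3 (SD 0.117) and Rpl22 (SD 0.0822). In the cell cycle list it was 0.216 ± 0.0163 and 12 of 16 followed, among them Ccna2 (r = 0.859, rho = 0.827), Ccnb2 (r = 0.853, rho = 0.826) and Birc5 (SD 0.220). The checkpoint kinase Bub1 ran against them (r = -0.359, rho = -0.400). Genes of endoplasmic reticulum stress had 0.170 ± 0.0167 and 11 of 13 followed, led by Sdf2l1 (r = 0.727, rho = 0.701, SD 0.161) and Hsp90b1 (r = 0.670, rho = 0.675), with Asns next in spread (SD 0.166). The oxidative stress response had 0.147 ± 0.0152 and 7 of 11 followed. The glutathione transferases Gstm1 (r = 0.645, rho = 0.613) and Gsta2 (r = 0.613, rho = 0.576, SD 0.252) led them, and the haem oxygenase Hmox1 did not follow (r = 0.0177, SD 0.381).

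The circadian clock list was not correlated on average (mean 0.0180, adjusted p = 0.171), and its genes went both ways. Per3 (r = 0.365, rho = 0.412) and Dbp (r = 0.268, rho = 0.259) were among 8 of 14 that followed. Arntl, the Bmal1 of the positive limb (r = -0.436, rho = -0.408, SD 0.223), and Nr1d1 (r = -0.318, rho = -0.304, SD 0.204) ran against them. Sex-biased liver genes did not pass within the marker clusters (mean 0.0737, adjusted p = 0.098), although 19 of 22 followed, led by Sult2a1 (r = 0.366, rho = 0.375) and the hydroxylase Cyp7b1 (r = 0.374, rho = 0.348). The relation of A1bg rested on the 2 farthest mice (r = 0.153, adjusted p = 0.0097, and p = 0.0843 without them), and Hao2 did not follow (r = -0.0479). The 3 genes with a known parental difference were not correlated (mean 0.0127, adjusted p = 0.494), and none of Nnt (r = 0.0517), Tlr4 (r = 0.0217) and Abcc6 (r = -0.0311) followed the others. Of the sex chromosome genes only Eif2s3y and Kdm5d were measured under a name, too few for a test.

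In all, 24 of the 30 lists tested passed, each against 10000 random lists of the same size and spread. Their adjusted p lay between 0.0002, the smallest these draws can give after adjustment, and 0.0124 for glucose metabolism, and the means of the random lists lay near 0. All 24 had a positive mean in each of the 4 blocks of mice defined by marker cluster and range of mouse numbers. Of 368 list members 314 followed or opposed the rest of their list in Pearson's r (permutation test, adjusted over the 368), 308 of them also in Spearman's rho, and 6 no longer did without the 2 farthest mice. Members were tested against permuted mice and not against random genes, and genes on different chromosomes also had a mean squared r of 0.0511. How many random genes would follow a list was not counted. For the genes given here with a rho and no p, the raw p was 1e-05 for r and, apart from Car3, Cel, Prss2 and Dbp (up to 0.00076), for rho, the smallest that the permutations can give, with an adjusted p of 1.38e-05 for r. Adjusted over the list alone the number following was the same in every list but that of the exocrine pancreas.

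**Figure D3:**
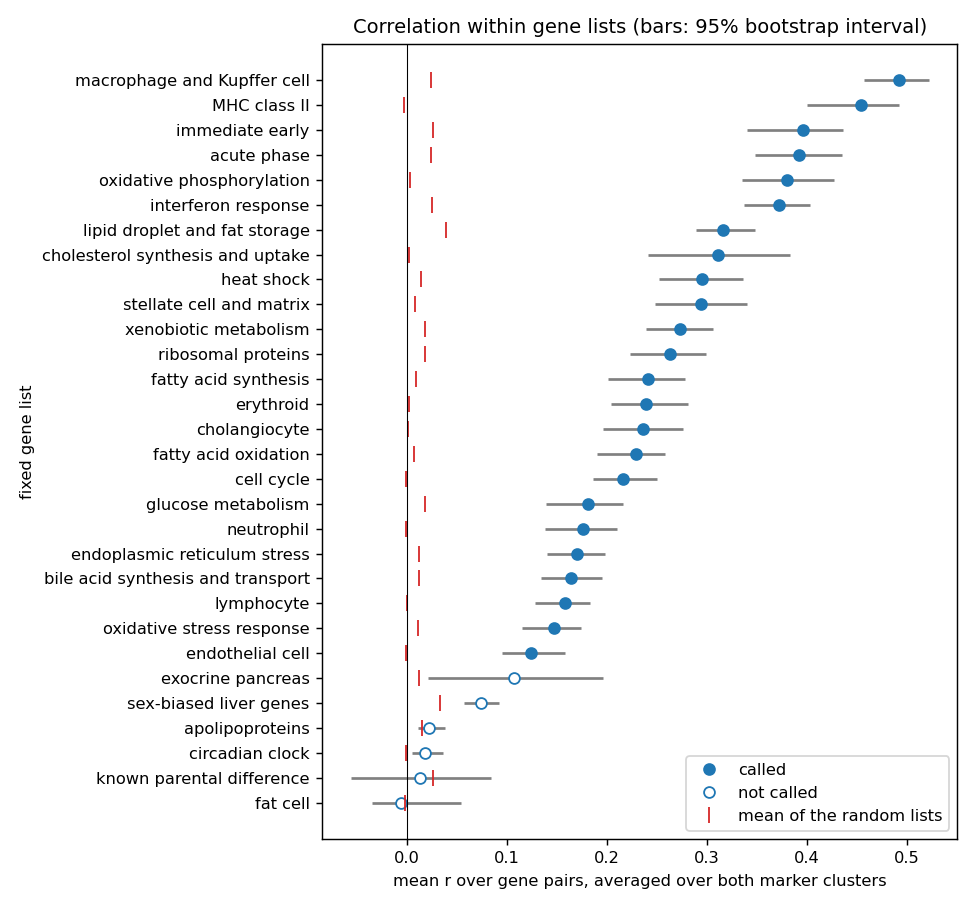
Mean Pearson correlation over all pairs of measured genes in each of 30 fixed lists, taken within each of the 2 marker clusters and averaged, with 95% bootstrap intervals over mice. Filled points are the 24 lists that passed, open points the 6 that did not, and red ticks the mean of the random lists, with the macrophage list highest at 0.492.

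Many of the single pairs of genes fixed beforehand followed each other closely. Pairs whose symbols start with the same letters, which were left out among adjacent genes, were kept here and in the lists. How far a shared place on a chromosome or a likeness between related genes adds to their r was not tested. S100a8 and S100a9, which form one protein complex, had r = 0.974 and 0.968 in the marker clusters of 142 and 160 mice (rho = 0.974 and 0.971), and Abcg5 and Abcg8, partners in sterol export, had 0.822 and 0.915 (rho = 0.806 and 0.901). Saa1 and Saa2 had 0.895 and 0.815 (rho = 0.922 and 0.872), C1qa and C1qb 0.824 and 0.803, Fasn and Acly 0.861 and 0.513, Pck1 and Tat 0.653 and 0.742. The clock genes Arntl and Dbp ran in opposite directions (r = -0.677 and -0.672, rho = -0.689 and -0.701), and so did Per2 and Nr1d1 by r (-0.220 and -0.369) but not by rho in the smaller cluster (-0.153 and -0.377, adjusted p = 0.081 and 1.45e-05). Hspa1a and Dnajb1 (0.557 and 0.723), Orm1 and Lcn2 (0.597 and 0.602) and Fos and Egr1 (0.612 and 0.509) also passed in both clusters. So did Scd1 and Elovl6 (0.612 and 0.454), Srebf1 and Fasn (0.621 and 0.372), Cd68 and Gpnmb (0.603 and 0.399), Top2a and Ccnb2 (0.428 and 0.282) and Hspa5 and Pdia4 (0.205 and 0.379). With the most variable probe of each gene the r of Top2a and Ccnb2, averaged over both clusters, went from 0.355 to -0.0248 and the pair did not pass.

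Of 40 fixed pairs 21 had both genes measured and 18 passed (permutation test in each cluster, adjusted over 42 tests, raw p down to 1e-05, the smallest possible). No random pairs were tested beside them, and genes on different chromosomes had a mean squared r of 0.0511. Passing thus does not set a weak pair apart from other genes. For Abcg5 and Abcg8, S100a8 and S100a9, and Saa1 and Saa2 the adjusted p was 1.4e-05 in both clusters, r stayed above 0.8 without the 2 farthest mice, and r ranged over the 4 blocks from 0.826 to 0.924, 0.967 to 0.976 and 0.849 to 0.929. The range was wider in weaker pairs: -0.0184 to 0.338 for Pecam1 and Cdh5, 0.0271 to 0.621 for Idi1 and Cyp51, 0.0944 to 0.434 for Hspa5 and Pdia4, 0.154 to 0.707 for Cd68 and Gpnmb, 0.173 to 0.582 for Srebf1 and Fasn and 0.336 to 0.685 for Orm1 and Lcn2. Idi1 and Cyp51 passed by r (0.289 and 0.418) but not by rho (0.120 and 0.148, adjusted p = 0.178 and 0.0741), and the higher r fell to 0.168 without the 2 farthest mice. Pecam1 and Cdh5 (0.183 and 0.182) did not pass by rho in the smaller cluster (0.0525, adjusted p = 0.561), and r went to 0.0685 there without the 2 farthest mice (p = 0.421), so the relation in that cluster rested on those mice. Pklr and Thrsp (0.0359 and -0.0308), Ppara and Cpt1a (0.0696 and 0.309) and Alas2 and Slc4a1 (0.367 and 0.0939) did not pass in both clusters.

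The number in a mouse's title is the only label that differs between mice, and many genes changed along it. The chemokine Cxcl1 rose by 0.268 ± 0.0195 log10 units (SE) per SD of the mouse number, a 1.85-fold step (limma, adjusted p = 9e-32). The activin subunit Inhbb rose by 0.232 ± 0.0167 (adjusted p = 2.34e-32), Lpin1, an enzyme of triglyceride synthesis, by 0.227 ± 0.0165 (9.73e-32), the thrombomodulin gene Thbd by 0.223 ± 0.0146 (8.6e-37) and the acute phase gene Saa3 by 0.210 ± 0.0195 (8.47e-22). The surface antigen Ly6d changed by -0.189 ± 0.0188 (1.75e-19), Cidea by -0.182 ± 0.0326 (1.79e-07), the receptor Gpr12 by -0.177 ± 0.0147 (6.15e-26), the collagen Col1a1 by -0.174 ± 0.0191 (1.08e-16) and the cornified envelope gene Sprr1a by -0.162 ± 0.0240 (3.9e-10). In the mice numbered 51 to 212 Cxcl1 had a mean of -0.188 ± 0.395 (SD, n = 159), and in those numbered 213 to 362 one of 0.217 ± 0.402 (SD, n = 143). Inhbb, Lpin1, Thbd and Sprr1a also passed the rule for separate clusters, so their slopes need not be an even change along the number. The lower cluster held 75 and 18 mice of these 2 ranges for Inhbb, 75 and 17 for Lpin1 and 78 and 13 for Thbd. For Sprr1a the upper cluster held 51 and 12.

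In several lists most genes had a slope of one sign, in counts that were drawn up after the data had been seen. No list was tested against the 66.9% of all probes that had a slope. Of 14 genes of drug metabolism 10 rose and none fell, and in the acute phase list 12 of 16 rose and 1 fell. In fatty acid oxidation 10 of 16 rose and 2 fell, and in bile acid synthesis and transport 8 of 13 rose and 1 fell. In cholesterol synthesis and uptake 12 of 16 fell and 1 rose, and in fatty acid synthesis 12 of 15 fell and 2 rose. Among macrophage genes 14 of 21 fell and 2 rose, and of 7 MHC class II genes 5 fell and none rose. Of 9 lipid droplet genes 5 fell and none rose. Other lists were mixed: 5 rose and 4 fell of 12 endothelial genes, 5 and 6 of 13 genes of endoplasmic reticulum stress, 5 and 7 of 13 apolipoprotein and lipoprotein genes and 4 and 7 of 14 stellate cell and matrix genes. None of 5 fat cell genes had a slope. Counted at an adjustment over the list alone, 10 genes passed in drug metabolism, 13 in the acute phase list, 13 in cholesterol synthesis and uptake, 14 in fatty acid synthesis and 17 among macrophage genes.

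With marker cluster as a covariate 15727 of 23512 probes (66.9%) had a slope (limma, Benjamini-Hochberg at 0.05), of which 8081 rose and 7646 fell. Most slopes were small, with a median size of 0.0178 log10 units per SD of the number (90.6), and 154 were over 0.1. The mice also fall into 2 ranges of numbers with different missing probes, and with that range as a further covariate 9175 probes passed, 7921 of them among the 15727. Slopes then rose to 0.382 for Cxcl1, 0.375 for Inhbb, 0.363 for Lpin1 and 0.327 for Thbd. They shrank to 0.161 for Saa3, -0.134 for Ly6d, -0.156 for Gpr12 and -0.0982 for Col1a1 (adjusted p = 0.0283), and these 8 passed. Cidea (-0.0508, adjusted p = 0.572) and Sprr1a (-0.0463, adjusted p = 0.471) did not.

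How well the arrays repeat a value is not known, since no mouse was measured again. Agreement between probes of 1 gene is given instead, and it depends on how much the gene varies as well as on the arrays. Over 1150 genes the median r between probes of a gene was 0.152 (95% bootstrap interval 0.132 to 0.172), against 0.00715 for random pairs of probes of similar spread (permutation p = 0.001, the smallest that 1000 draws can give, one-sided). It was 0.409 with only probes over the median SD, 0.604 in the 115 genes in the upper 10% of spread and 0.0981 in the lower 50%. In 21.4% of the genes it was over 0.5 and in 25.2% below 0.

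Some genes that lie next to each other on a chromosome were closely correlated. On chromosome 17 Phf1, a chromatin protein gene, and Bak1, an apoptosis effector, had r = 0.911 (rho = 0.836), and on chromosome 10 the trafficking gene Gcc2 and the nuclear pore gene Ranbp2 had r = 0.909 (rho = 0.870). On chromosome 11 the ubiquitin enzyme gene Ube2b and the phosphatase subunit Ppp2ca had r = 0.881 (rho = 0.829), and Timd2 and Havcr1, receptors of one family, r = 0.856 (rho = 0.864). On chromosome 1 the coagulation factor subunit F13b and Gm4788 had r = 0.853 (rho = 0.834). Each of these r had a permutation p of 1e-05, the smallest possible, stayed at 0.840 or more without the 2 farthest mice, and was at least 0.749 in every block. They are the highest of 9766 adjacent pairs and were picked for it. A high r was not particular to adjacent genes. Ranbp2 had r = 0.909 with Ascc3, 19 places away, and 0.781 with Cd164, 39 places away, both named after their values were seen.

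Over 10806 genes, ordered by a mouse gene table of the assembly GRCm38.p6, adjacent genes had a mean squared r of 0.0607, against 0.0511 for pairs on different chromosomes. The difference of 0.00957 was larger than in any of 1000 orders of the genes (permutation p = 0.001, the smallest possible, one-sided). It fell with the number of places between the genes, to 0.00446 at 2 to 5 places, 0.00234 at 6 to 20 and 0.00122 at 51 to 100, and was -0.000251 at 201 to 400. Of 404 adjacent pairs with a squared r over 0.25, 346 were positive.

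**Figure D4:**
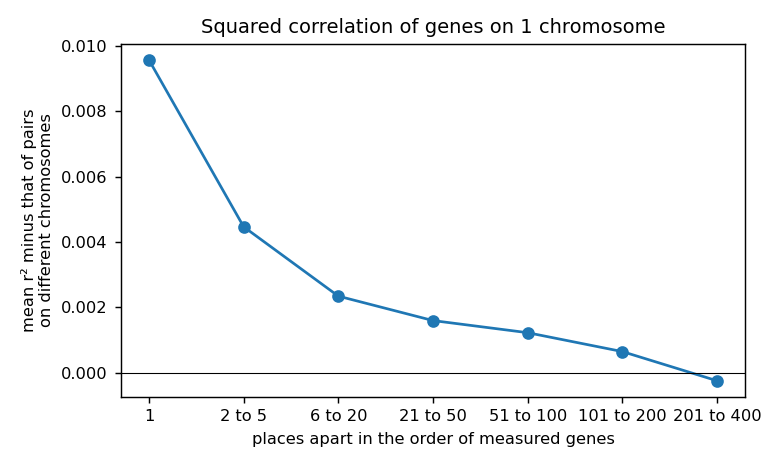
Mean squared correlation of gene pairs on a chromosome minus that of pairs on different chromosomes, by the number of places between the genes in the order of measured genes. The points fall from 0.00957 for adjacent genes to -0.000251 at 201 to 400 places.

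If the pool holds equal shares of all mice, as described, the mean ratio against it should lie near 0. Dye bias and the difference between a mean of logs and the log of a mean can move it, and other sources may too. Their parts were not tested. Several of the genes with the largest SD lay below the pool on average. A mean of logs falls below the log of a mean as spread grows, and the direction of the ratio was read from this property. Their low means are therefore no separate result. The mean log10 ratio was -0.945 for A1bg, -0.878 for Cidea, -0.746 for Sult2a1, -0.703 for Eif2s3y and -0.593 for Sult3a1 (n = 302 each). In all, 275 probes had a mean over 0.1 in size and differed from 0 (limma, Benjamini-Hochberg at 0.05), 271 of them below and 4 above, and 269 of them varied widely. This mean ratio against the pool was not the same along the mouse numbers: 183 probes passed in the lower 50% of them, with 0 above, and 1014 in the upper 50%, with 249 above. Without a limit on size 16428 probes differed from 0, of which 66.3% were above the pool as deposited and 54.2% with each array centred on its median. In the lower and the upper 50% of numbers 4058 and 17887 did, with 76.7% and 59.8% above. Similar counts would be looked for in both if all mice were measured alike against 1 pool of equal shares, so this premise stays open.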

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

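The removal of block means, marker cluster means and slopes, the covariate for the range of numbers, the limit of 10% and the dip were chosen after the results were seen. Of the counts and medians that answer a comparison, 79 alternative values stayed within 1.5 times or on the same side of the threshold and 14 did not. Across the former, the lists that passed numbered 24 to 26, pairs 13 to 18, widely varying probes 1504 to 1913, probes with separate clusters 780 to 1274, probes with a slope 15087 to 16275 and means against the pool 260 to 299. The median r between probes of a gene lay between 0.140 and 0.409, the highest with both probes over the median SD. The excess of neighbouring genes lay between 0.00446 for genes 2 to 5 places apart and 0.0131 for adjacent genes when pairs with the same starting letters were kept. Relatives with unlike symbols, such as Timd2 and Havcr1, remain in the main value of 0.00957. Of the values of the SD of the 25 named genes 154 stayed inside its interval and 121 did not, among them all 25 with the median absolute deviation. The cause of the shifts that follow was not tested except where a smaller number of mice or another limit makes them.

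The probes that vary widely among mice numbered 514 at 3 times the median SD. The probes with separate clusters of mice numbered 2441 at a separation over 2 SDs, 153 over 4 SDs, and 652 with extreme values pulled in. There were 655 with the means of the 4 blocks removed, 600 with the slope on the number removed in each block, 491 with a smaller component of at least 10% and 99 with a dip. The probes that drift with mouse number were 9175 with the range of numbers as a covariate, 8683 in the lower and 2367 in the upper 50% of mouse numbers. For the mean ratio against the pool the count was 1215 at a limit of 0.05, of which 163 were above. It was 183 and 1014 in the lower and the upper 50% of numbers, of which 0 and 249 were above.

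Results that changed sign were near 0 or not called in the fixed setting, apart from Top2a and Ccnb2, whose r went to -0.0248 with the most variable probe of each gene. The mean r of fat cell genes was 0.0222 without the arrays that stand apart, 0.0216 in the upper 50% of numbers, 0.0273 with extreme values pulled in, 0.0270 by Spearman's rho and 0.0256 over pooled mice. That of the genes with a parental difference was -0.0115 with quantile normalization and -0.00446 in the lower 50% of numbers, that of sex-biased genes -0.00811 over pooled mice, and the mean r of circadian clock genes -0.00141 with 5 principal components removed. The r of Pklr and Thrsp was -0.00521 without the arrays that stand apart, -0.168 in the lower 50% of numbers and -0.0144 with the block means removed. Among single lists and pairs, 1 and 16 values fell under the threshold and 8 and 1 rose past it, and 402 and 231 stayed on their side. Signal over background is not part of the deposited table, so its effect on weak probes could not be examined.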

Other observations

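The correlations between lists, the weighing of a lower share of hepatocytes and of the blocks for the macrophage and bile acid lists, and the tests on the probes near 1:3 and with block means removed were set up only after the results they build on had been seen. Across mice, livers with higher values of macrophage genes also had higher values of MHC class II genes (r = 0.757, rho = 0.712), stellate cell and matrix genes (r = 0.618, rho = 0.580) and lipid droplet genes (r = 0.516, rho = 0.516). Lipid droplet genes rose with stellate cell and matrix genes (r = 0.608, rho = 0.621, 0.428 to 0.699 over the blocks) and with oxidative stress genes (r = 0.494, rho = 0.459). Genes of cholesterol and of fatty acid synthesis moved together (r = 0.709, rho = 0.667), and fatty acid synthesis ran against the acute phase (r = -0.415, rho = -0.462). Bile acid and drug metabolism genes moved together (r = 0.737, rho = 0.718).

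Running the other way, bile acid genes were lower where macrophage genes were higher (r = -0.609, rho = -0.589) and so were drug metabolism genes (r = -0.436, rho = -0.411). Lipid droplet genes ran against bile acid genes (r = -0.497, rho = -0.50). Each of these had an adjusted p of 3.36e-05 over 434 pairs of lists (permutation test, raw p = 1e-05, the smallest possible) and the same sign in all 4 blocks. Without the 2 farthest mice, macrophage and bile acid genes had r = -0.595 and macrophage and MHC class II genes 0.733. In all, 243 pairs of lists passed, 123 of them negative, 233 also by rho and 195 with the same sign in every block, and 5 did not hold without the 2 farthest mice. Pairs of random lists were not tested, so the counts do not show a relation particular to these lists. These correlations also kept any slope on the mouse number that the lists share.

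Among probes with separate clusters, an inherited variant near each gene, a sequence difference under the probe and separate processing of the blocks were weighed. Differences between block means are not the whole source, since 461 of the 652 probes (70.7%, 67.1 to 74.2, taking probes as independent, which they are not) also had separate clusters once these means were removed. Removing a mean leaves a subset of mice inside a block in place, and a single skewed distribution passes the rule too. Processing of some mice within a block therefore stays open. The blocks may act in part, since membership followed the range of mouse numbers in 58.1% (54.2 to 62.0) and in 31.1% (22.3 to 40.9) of the 103 probes near 1:3. Joint inheritance stays open for the set as a whole, where genes within 50 places exceeded those on different chromosomes in squared r by 0.00848 (-0.0108 to 0.0305, 513 pairs): the bound set in advance, an interval that includes 0, was too weak, as this one also reaches past the 0.00957 of all adjacent genes. Among the 103 the difference was 0.301 (0.115 to 0.472, 12 pairs) and within the blocks 0.288 (0.107 to 0.471), so that linked variants may underlie some of these states, as in Rps3 and Folr2 (r = 0.848), but Rb1cc1 and Ptp4a1, which follow the range, fell from 0.673 to 0.429 within blocks and pairs such as Gcsh and Klhl36 (0.0366), Synpo2 and Eif4e (-0.0750) and Gpr182 and Cd63 (0.110) lay near 0. A variant under the probe cannot be told apart from a change in RNA, since the median r with the gene's other probes was 0.205 (0.138 to 0.361, 68 genes) and the interval spans the 0.3 set in advance.

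For the opposition of macrophage and bile acid genes, a lower share of hepatocytes in the piece of liver, array quality and the blocks were weighed. Differences between the blocks are argued against, since r was -0.522 (-0.712 to -0.304) in the block nearest to 0. A slope on the mouse number within the blocks stays open, since it was not removed. Along the number 14 of 21 macrophage genes fell and 2 rose, while 8 of 13 bile acid genes rose and 1 fell. A lower share of hepatocytes stays open: markers of 5 other cell types all rose with the macrophage list, with the lowest mean r for neutrophils (0.250, from 0.291, 0.127 to 0.446, and 0.209, 0.0530 to 0.347, in the marker clusters), which is consistent with it. Array quality stays open too, since r went to -0.0958 (-0.201 to 0.0193) once the first 5 principal components of all other probes were removed, and these components may hold biology as well as quality. No biological explanation was tested, because the labels give no trait of a mouse.

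For the slopes on mouse number, a chance order of single mice is argued against. Of the 23324 probes without a missing value 15690 had a slope in the real order. The highest of 100 permuted orders gave 0, so that 1 of 101 orders was as large. These orders took neighbouring mice as independent, so chance among runs of mice, such as litters or dates, was not tested. Separate processing of the 2 ranges is not the whole source, since with the range as a covariate the count was 58.3% as large and 7921 of the 15727 probes called without it passed again. What the number orders is not stated, so date, litter or a batch that follows the number within a range could each be a source of the slopes.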
